A study of Mus musculus with 6 samples.

How the data were processed

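The data are RNA sequencing of 6 libraries of mouse alveolar macrophages. Per the labels' protocols, total RNA was taken from 50000 macrophages sorted from lavage fluid for each sample, libraries were made with a stranded SMART-Seq kit, and single-end reads of 100 bp were sequenced on an Illumina instrument. Such a kit amplifies complementary DNA by PCR, and no molecular identifiers are named in the labels, so the counts are of reads and not of distinct molecules. Counting limits given here therefore cover counting error only.

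The values used are the gene counts that the authors deposited, 1 table with 25664 genes by symbol and 1 column per library, and they are whole numbers that sum to different totals in each library. Per the submitters' processing notes, the tools were STAR, featureCounts, R 4.3.2 and DESeq2 1.40.1, and the genome builds were GRCm38.p5 and mm10. The notes used here give these names without their order. The versions of the aligner and the counter, the annotation and the strand setting of the counting are not given in the sources used here. Reads from antisense or overlapping genes can therefore not be told apart from those of the named gene, and genes with near-identical copies are reported as uncertain. The share of a gene's 100-base words, taken from its longest transcript, that also occurs in another gene was counted in GENCODE mouse release 21. Symbols of 24893 genes were matched to that annotation directly and 127 through older names, while 644 stayed without a match. Coordinates are from the same release, which is on GRCm38.

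Each library was placed in its group by its genotype label, and replicate numbers were taken from the titles. Nothing in the labels says whether the samples came from separate mice, so p-values measure only the spread between these samples, which may in part be technical. No pair of libraries held identical or near-identical counts. Genes were kept for testing by the default rule of edgeR (filterByExpr, minimum count 10, minimum total 15), which left 11011 genes. Libraries were scaled with trimmed mean of M values (TMM) factors. Levels are CPM from edgeR's cpm function, on the scaled library sizes, given as mean ± SD with n = 3 per group. The levels of markers of other cells near 0 are CPM of the unscaled library totals, as is the level of 3 counts. Pex5-deficient was compared with control by edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are Pex5-deficient over control, and their standard errors were derived from the F statistics. Every adjusted p of a gene comes from this test unless another tool is named.

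Before the data were examined, 39 gene lists were fixed: pathways of peroxisomes, lipids, mitochondria, stress and macrophage function, a list of immediate early genes as a sign of handling, and markers of 10 kinds of other cells that lavage fluid or a sort could hold. The 32 lists with at least 5 tested members were ranked with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the data and fry were run beside it. With the estimated correlation 0 of the 32 lists passed, and with fry only the neutrophil markers passed, so the calls of the other lists rest on the preset correlation. For each list the members called over all genes and those called when adjusted over the list alone are given. The genes named were fixed by rule at the same time: Pex5; the 12 genes called in each direction with the largest change, and the 5 with the smallest p, among those with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes, pseudogenes and receptor segments; and the 4 members of each list with the smallest p, or 2 and the most abundant member for marker lists. Some genes that this rule picks are not used here, although the counts given for their lists include them. A few other genes are named because of their place in a list or after their values were seen, which is said where they appear in the closing section. In the text on the comparison these are Pparg, Chil3, Marco, Ear2, Mylip, Pltp, H2-Ab1, Gpnmb, Mmp8 and Gsr, and markers of other cells that are given by level.

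Shares of counts, library totals and detected genes were compared with an exact permutation test of 3 against 3 libraries, two-sided, whose smallest possible p is 0.1. Enrichment of calls by position was tested with Fisher's exact test, and intervals of list medians are 95% bootstrap intervals over genes with 10000 resamples. The steps were tested on simulated data drawn from the means, dispersions and library sizes of this comparison, with 200 changed genes in each of 5 simulations and 10925 genes tested on average. At a 1.5-fold change 15.2% of changed genes were recovered, at 2-fold 71.3% and at 4-fold 96.9%, and 6.52% of calls were false with 0 in the wrong direction. Changes well under 2-fold were therefore often missed at this depth and spread. Of 160 list tests on simulated data without a change 1 was called, and a list shifted 1.5-fold was found in 5 of 5 simulations. The simulated genes vary independently of each other, unlike real ones.

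Alternatives, fixed together with the lists, were other scalings (DESeq2 size factors, upper quartile, library size only), no filter and a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, the robust form of the edgeR test, the replicate number as a block, a loess offset for GC content and gene length (span 0.5) with and without that block, leaving out mitochondrial, ribosomal protein and haemoglobin genes, a prior count of 0.5, and leaving out each library in turn. GC content and length were known for 99.3% of tested genes. Sex as a covariate was planned where both sexes occurred. Transcripts of the Y chromosome were expressed in all 6 libraries, so this model could not be fitted.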

Results

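RNA was sequenced from alveolar macrophages, the resident phagocytes of the lung's airspaces, sorted from lavage fluid of mice. 3 libraries came from Vav1cre/+ Pex5fl/fl mice and 3 from Pex5fl/fl mice without the recombinase. Vav1-Cre is active in blood-forming cells and their progeny, macrophages included, and the groups are called Pex5-deficient and control. PEX5 is the receptor that brings most matrix enzymes into peroxisomes, the organelles that shorten very long-chain and branched fatty acids, begin ether lipid synthesis and handle hydrogen peroxide. Total counts were 13325609, 17814958 and 19413838 in Pex5-deficient replicates 1 to 3 and 14226108, 18987200 and 14346831 in control replicates 1 to 3. At least 1 count was found for 13200 to 13840 genes per library. The first principal component of log2 CPM held 47.6% of the variance and separated the groups. Pex5-deficient replicate 2 stood apart from the other libraries. The 50 genes most abundant on average over all libraries took 30.4% of its counts, against 38.3% to 42.1% in the others, and its scaling factor was 1.34, against 0.90 to 1.03.

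The targeted gene was not lower in the counts. Pex5, on chromosome 6 from 124396816 to 124415067 (GRCm38), measured 31.6 ± 1.71 CPM in control and 32.4 ± 3.45 CPM in Pex5-deficient macrophages, with single libraries at 33.0, 32.1 and 29.7 CPM in control replicates 1 to 3 and 31.4, 36.3 and 29.6 CPM in Pex5-deficient replicates 1 to 3. The log2 fold change was 0.04 ± 0.11 (SE, n = 3 per group, adjusted p = 0.891), with a 95% interval from -0.21 to 0.29. A floxed allele loses only the exons between its loxP sites, and a count over the whole gene keeps the reads of the exons that remain. Which exons are removed is not given in the sources used here, so these counts do not check the genotype labels.

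The comparison asks what differs in the transcripts of alveolar macrophages from the mice labelled Vav1cre/+ Pex5fl/fl, in a study of what peroxisomes do for the metabolism and survival of these cells. Pex5-deficient macrophages had less transcript of Siglecf, the sialic acid-binding receptor by which alveolar macrophages are recognised, which fell from 651 ± 28.6 to 219 ± 39 CPM (mean ± SD, n = 3 per group). Csf2rb2, the second beta chain of mice, which serves the receptor for IL-3, fell from 298 ± 25.4 to 100.2 ± 16.6 CPM, and Fabp1, a carrier of fatty acids, fell from 409 ± 142 to 71.6 ± 18.1 CPM. Trem2, a receptor for lipids and apoptotic cells, rose from 52.7 ± 10.7 to 203 ± 39.2 CPM, and Igf1, a growth factor, from 23.9 ± 10.1 to 179 ± 49.1 CPM. Fstl1, a secreted glycoprotein on chromosome 16 from 37776873 to 37836514, rose from 0.769 ± 0.492 to 72.8 ± 40.6 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 358 of 11011 genes were called, 192 higher and 166 lower, and 215 of them differed at least 2-fold, 127 higher and 88 lower. At an unadjusted p under 0.05 there were 2078 genes, and for 2870 genes (26.1%) the groups did not overlap, where chance alone gives 10%. The count of calls was 117 without Pex5-deficient replicate 1, 219 without replicate 3, 76 without control replicate 1, 181 without control replicate 2 and 136 without control replicate 3, and 523 without Pex5-deficient replicate 2. The count of calls of at least 2-fold was 102 without Pex5-deficient replicate 1, 68 without control replicate 1 and 120 without control replicate 3. 68 genes, 35 higher and 33 lower, kept their call whichever library was left out. Scaling by library size alone moved the median log2 fold change of all genes by 0.17. It called 289 genes higher and 132 lower, with 240 of the 358 among them. DESeq2 called 755, the 358 among them.

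**Figure D1:**
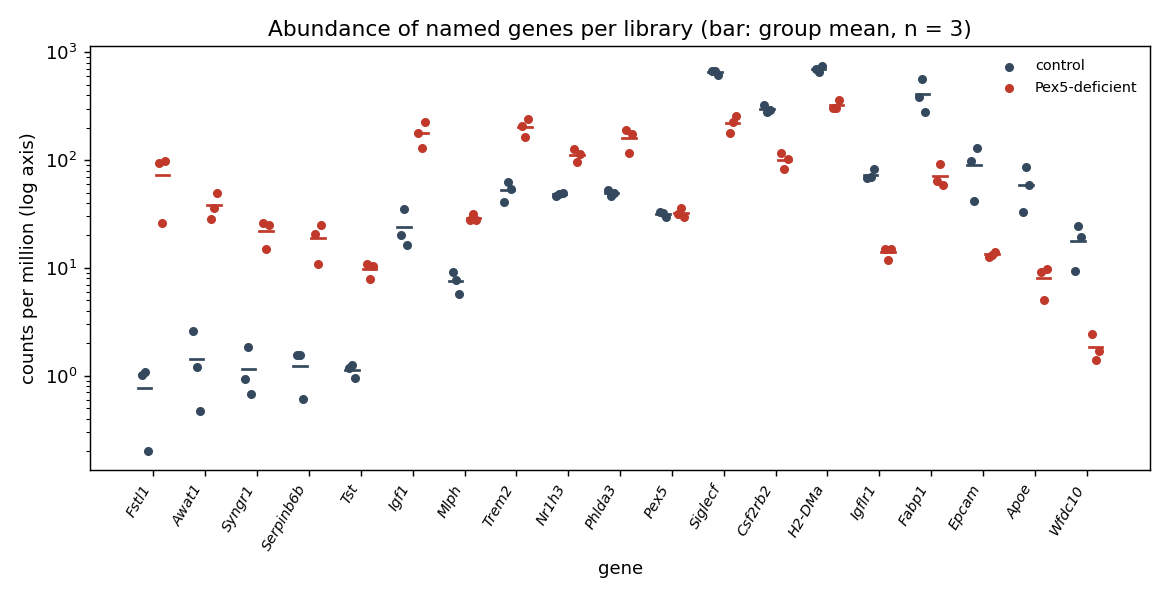
Abundance of 19 named genes in CPM (log axis), 1 point per library and a bar at the group mean (n = 3 control, dark; n = 3 Pex5-deficient, red). Fstl1 stood at 0.769 CPM in control and 72.8 CPM in Pex5-deficient macrophages, Siglecf at 651 and 219 CPM, and Pex5 at 31.6 and 32.4 CPM.

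Among the genes that the naming rule allows, those with the largest rise, after Fstl1, had varied functions. Called genes outside that rule reached an absolute log2 fold change of 9.74. Awat1, an acyltransferase that makes wax esters, rose from 1.42 ± 1.07 to 38.2 ± 10.6 CPM (log2 fold change 4.79 ± 0.42, adjusted p = 0.00242), and Tst, a mitochondrial sulfurtransferase, from 1.13 ± 0.163 to 9.76 ± 1.59 CPM (3.10 ± 0.24). Plpp3, a lipid phosphate phosphatase, had a log2 fold change of 2.80 ± 0.45. Pla2g16, a phospholipase named for its small p, had a smaller one of 1.23 ± 0.11 (adjusted p = 0.00242). Mfge8, which bridges apoptotic cells to phagocytes, rose from 9.53 ± 0.832 to 136 ± 98 CPM, and Wfdc17, a secreted protein of activated macrophages, from 31.1 ± 12.6 to 342 ± 172 CPM. Syngr1, a synaptic vesicle protein, rose from 1.15 ± 0.607 to 22.1 ± 6.34 CPM, the protease inhibitor Serpinb6b from 1.24 ± 0.547 to 18.9 ± 7.28 CPM, and Mlph, a myosin adaptor likewise named for its small p, from 7.5 ± 1.67 to 29.1 ± 2.34 CPM. The chemokine genes Ccl3 (2.88 ± 0.43) and Cxcr1 (2.89 ± 0.49), the latter a chemokine receptor, and the cell cycle regulator Rgcc (2.94 ± 0.45) also rose. Mfge8 lost its call without control replicate 1 (0.0678) or 2 (0.0522), the adjusted p standing in parentheses. Wfdc17 lost its call without control replicate 1 (0.0566). Rgcc lost its call without control replicate 1 (0.0635). Cxcr1 lost its call without Pex5-deficient replicate 1 (0.0721) and control replicate 1 (0.0541) or 3 (0.0729). Ccl3 lost its call without control replicate 1 (0.0681). Plpp3 lost its call without Pex5-deficient replicate 1 (0.0646) and control replicate 1 (0.0834). Fstl1, Awat1, Syngr1, Serpinb6b, Tst, Igf1, Pla2g16 and Mlph kept theirs without any 1 library.

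Under the same rule, the genes with the largest fall had varied functions too. Apoe, the lipoprotein that carries cholesterol out of macrophages, fell from 59.3 ± 26.2 to 7.98 ± 2.6 CPM (log2 fold change -2.92 ± 0.37, adjusted p = 0.00703), and Wfdc10, a small secreted protein, from 17.7 ± 7.59 to 1.84 ± 0.533 CPM (-3.31 ± 0.38). Epcam, an adhesion molecule known best from epithelium, fell from 89.9 ± 44.2 to 13.3 ± 0.577 CPM, the adhesion protein gene Emb from 59 ± 17.8 to 8.26 ± 2.14 CPM and the matrix protein gene Ccdc80 from 115 ± 52.8 to 17.6 ± 3.91 CPM. Gpd1, which joins glycolysis to glycerolipid synthesis, fell from 30 ± 3.81 to 5.96 ± 2.13 CPM, Klhl3, an adaptor of protein ubiquitination, from 10.7 ± 2.41 to 1.5 ± 0.275 CPM, and Mcub, an inhibitory subunit of the mitochondrial calcium uniporter, from 35.9 ± 2.88 to 12.3 ± 2.26 CPM. The smallest adjusted p of all, 0.000505, belonged to Igflr1, a receptor of the tumour necrosis factor receptor family on chromosome 7 from 30565427 to 30567962, which fell from 73.3 ± 8.61 to 14 ± 1.79 CPM (-2.39 ± 0.14). A longer predicted gene overlaps Igflr1 and holds 91.4% of its 100-base words, so this value is uncertain. Ear1, an eosinophil-associated ribonuclease abundant in alveolar macrophages, had a log2 fold change of -2.52 ± 0.48, and the class I MHC genes H2-Q7 and H2-Q6 had -2.48 ± 0.40 and -2.33 ± 0.43. These 3 shared 17.3%, 12.4% and 10.7% of their words with other genes, their closest partners being copies of the same family, and are uncertain as well. Ear1 lost its call without Pex5-deficient replicate 1 (0.135) and control replicate 1 (0.118) or 2 (0.0911). H2-Q7 lost its call without control replicate 1 (0.0716) or 2 (0.0544). H2-Q6 lost its call without control replicate 1 (0.105), 2 (0.0754) or 3 (0.0524). Wfdc10, Apoe, Emb, Klhl3, Epcam, Ccdc80, Fabp1, Igflr1, Gpd1, Csf2rb2 and Mcub kept theirs without any 1 library.

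Of 28 tested genes of alveolar macrophage identity, 5 fell and 2 rose, and 7 and 4 when adjusted over the list alone. Siglecf (-1.57 ± 0.16), Fabp1 (-2.51 ± 0.28), Krt79, a keratin (-1.44 ± 0.25), Ear1 (-2.52 ± 0.48) and the lipid droplet gene Cidec (-0.83 ± 0.18) were the lower ones. Ctsk, a lysosomal protease, rose from 681 ± 67.9 to 2217 ± 847 CPM and Fabp4, a fatty acid carrier, from 73.5 ± 37 to 203 ± 42.8 CPM. Pparg, the transcription factor on which the identity of these cells depends, differed by 0.07 ± 0.11 (adjusted p = 0.795), and Chil3, the most abundant of the list's named members, by 0.16 ± 0.55 (adjusted p = 0.91). Marco, a scavenger receptor, had -0.84 ± 0.47 and Ear2 -1.58 ± 0.40, neither called over all genes. Ear2 shares 13.9% of its words with a copy and is uncertain, as is Ear1 with 17.3%. The list ranked lower by camera (median log2 fold change -0.35, adjusted p = 0.0167), and adjusted p = 0.780 with an estimated correlation. Its call ended without Pex5-deficient replicate 2, the library that stood apart (median -0.15, adjusted p = 0.272), and without control replicate 2 (0.144). The median was -0.21 with scaling by library size alone. Siglecf and Fabp1 kept their calls without any 1 library. Krt79 lost its call without Pex5-deficient replicate 1 (0.10) or 3 (0.0548) and control replicate 1 (0.0978) or 2 (0.0605). Ear1 lost its call without Pex5-deficient replicate 1 (0.135) and control replicate 1 (0.118) or 2 (0.0911). Cidec lost its call without Pex5-deficient replicate 1 (0.155) or 3 (0.113) and control replicate 1 (0.172), 2 (0.117) or 3 (0.149). Ctsk lost its call without Pex5-deficient replicate 1 (0.0893) and control replicate 1 (0.13), 2 (0.0831) or 3 (0.0986). Fabp4 lost its call without Pex5-deficient replicate 1 (0.121) or 3 (0.0963) and control replicate 1 (0.185) or 3 (0.104).

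In the GM-CSF and TGF-beta axis 3 of 18 tested genes fell and 0 rose, and 4 fell and 1 rose when adjusted over the list alone: Csf2rb2 (-1.57 ± 0.15, adjusted p = 0.00258), Csf2rb, the beta chain shared by the receptors for GM-CSF, IL-3 and IL-5 (-0.88 ± 0.15), and Tgfbr1, a TGF-beta receptor (-0.88 ± 0.18). Bhlhe41, a repressor active in these cells, had 0.83 ± 0.21 (adjusted p = 0.0753). Csf2rb2 and Csf2rb share 7.20% and 6.96% of their words with each other and are uncertain in part. The list was not called (median -0.20, adjusted p = 0.0601, and adjusted p = 0.694 with an estimated correlation). It passed with DESeq2 (0.00344), limma-voom (0.0369), upper-quartile factors (0.0485), library size only (0.0491) and a mean of at least 5 CPM (0.0454). It also passed without Pex5-deficient replicate 1 (0.0322), control replicate 1 (0.0427) and control replicate 3 (0.0275). Csf2rb lost its call without Pex5-deficient replicate 1 (0.0793) or 3 (0.0546) and control replicate 1 (0.115), 2 (0.0849) or 3 (0.0768). Tgfbr1 lost its call without Pex5-deficient replicate 1 (0.139) or 2 (0.0545) and control replicate 1 (0.133) or 2 (0.105).

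Of 14 tested targets of the liver X receptors (LXR), which sense oxidised cholesterol, 5 fell and 1 rose, and 6 and 2 when adjusted over the list alone. Apoe (-2.92 ± 0.37), Abca1, the cholesterol efflux pump (-1.61 ± 0.24), Mylip, a ubiquitin ligase (-0.85 ± 0.16), Pltp, a phospholipid transfer protein (-0.69 ± 0.13), and Lpcat3, a phospholipid acyltransferase (-0.62 ± 0.11), fell. Nr1h3, which encodes LXR-alpha itself, rose from 48.1 ± 1.65 to 112 ± 15.1 CPM (1.22 ± 0.12, adjusted p = 0.00314). The list ranked lower by camera (median -0.65, adjusted p = 0.00357), and adjusted p = 0.694 with an estimated correlation. Apoe and Nr1h3 kept their calls without any 1 library. Abca1 lost its call without Pex5-deficient replicate 1 (0.0523) and control replicate 1 (0.0657). Mylip lost its call without Pex5-deficient replicate 1 (0.10) and control replicate 1 (0.115) or 3 (0.0963). Pltp lost its call without Pex5-deficient replicate 1 (0.129) or 3 (0.0511) and control replicate 1 (0.129), 2 (0.116) or 3 (0.0852). Lpcat3 lost its call without Pex5-deficient replicate 1 (0.0968) and control replicate 1 (0.111), 2 (0.0631) or 3 (0.0986).

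Cholesterol synthesis leaned the other way. Of 24 tested genes 1 rose and 0 fell, the same counts as when adjusted over the list alone: Dhcr7, the last enzyme of the pathway, from 65.2 ± 5.36 to 95.6 ± 10.6 CPM. Insig1 (0.53 ± 0.17) and Msmo1 (0.58 ± 0.19) were not called. The list ranked higher by camera (median 0.21, adjusted p = 0.00988), and adjusted p = 0.841 with an estimated correlation. The call ended without Pex5-deficient replicate 1 (adjusted p = 0.0795), Pex5-deficient replicate 2 (0.0985), control replicate 1 (0.0515) and control replicate 3 (0.253), and the median was 0.34 without Pex5-deficient replicate 3 and 0.39 without control replicate 2. It was 0.40 with scaling by library size alone. Dhcr7 lost its call without Pex5-deficient replicate 1 (0.147) or 3 (0.0907) and control replicate 1 (0.177), 2 (0.0886) or 3 (0.132).

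In fatty acid synthesis and desaturation 1 of 15 tested genes rose and 1 fell, and 1 and 2 when adjusted over the list alone. Elovl6, which lengthens saturated fatty acids, fell from 7.74 ± 2.87 to 2.22 ± 0.513 CPM. Hacd2, a dehydratase of fatty acid elongation, rose from 21.7 ± 1.72 to 31.3 ± 2.89 CPM. Acly (-0.51 ± 0.12) and Elovl5 (-0.34 ± 0.12) were not called, nor was the list (median -0.08, adjusted p = 0.607). Among 21 tested PPAR target genes, Fabp1, Acaa1b (-1.03 ± 0.19) and Cidec (-0.83 ± 0.18) fell and Fabp4 (1.46 ± 0.32) rose, 6 falling and 1 rising when adjusted over the list alone, and the list was not called (median -0.13, adjusted p = 0.0894, but 0.0421 without Pex5-deficient replicate 3 and 0.00654 with DESeq2). Sphingolipid metabolism had 0 calls among 18 tested genes over all genes and 0 when adjusted over the list alone (median -0.03, adjusted p = 0.826), with Sgms1 at 0.33 ± 0.14, Cers5 at -0.19 ± 0.09, Sptlc1 at -0.16 ± 0.09 and Smpd1 at 0.20 ± 0.12. Elovl6 lost its call without Pex5-deficient replicate 1 (0.0511) or 3 (0.0533) and control replicate 2 (0.053) or 3 (0.0518). Hacd2 lost its call without Pex5-deficient replicate 1 (0.155) or 3 (0.0887) and control replicate 1 (0.118), 2 (0.131) or 3 (0.135). Acaa1b lost its call without Pex5-deficient replicate 1 (0.111) or 3 (0.065) and control replicate 1 (0.118) or 2 (0.0927). Cidec lost its call without Pex5-deficient replicate 1 (0.155) or 3 (0.113) and control replicate 1 (0.172), 2 (0.117) or 3 (0.149). Fabp4 lost its call without Pex5-deficient replicate 1 (0.121) or 3 (0.0963) and control replicate 1 (0.185) or 3 (0.104).

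Of 15 tested factors of peroxisome biogenesis 0 were called, and 1 higher when adjusted over the list alone, Pex11a, which divides peroxisomes (0.75 ± 0.18, adjusted p over all genes = 0.0648). Pex7, the import receptor for the other targeting signal, had 0.30 ± 0.09, Pex16 0.18 ± 0.10 and Pex6 0.40 ± 0.26, and the list was not called (median 0.03, adjusted p = 0.278). Of 25 tested genes of peroxisomal beta- and alpha-oxidation 2 fell and 0 rose, and 3 fell when adjusted over the list alone. Hsd17b4, the multifunctional enzyme of the pathway, fell from 379 ± 35.9 to 209.9 ± 7.07 CPM (-0.85 ± 0.12), and Acaa1b, a thiolase, from 591 ± 115 to 290.4 ± 45.3 CPM (-1.03 ± 0.19). Acaa1a (-0.54 ± 0.14) was not called over all genes, nor was the list (median -0.03, adjusted p = 0.472). Acaa1b shares 21.9% of its words with Acaa1a and Tmem189 26.7% with a predicted gene, so both are uncertain. In ether lipid synthesis 1 of 11 tested genes rose, and 2 when adjusted over the list alone: Chpt1, a choline phosphotransferase, from 8.79 ± 2.22 to 26.3 ± 5.3 CPM (1.58 ± 0.21, adjusted p = 0.00865). Tmem189, which makes plasmalogens from their precursors, had 0.84 ± 0.23, Dhrs7b 0.32 ± 0.14 and Far1 -0.54 ± 0.25, and the list was not called (median 0.03, adjusted p = 0.217). Chpt1 kept its call without any 1 library. Hsd17b4 lost its call without control replicate 1 (0.0566). Acaa1b lost its call without Pex5-deficient replicate 1 (0.111) or 3 (0.065) and control replicate 1 (0.118) or 2 (0.0927).

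All 9 tested transcripts of the mitochondrial genome had lower means. 2 fell over all genes and 5 when adjusted over the list alone: mt-Nd6 from 109.6 ± 34.3 to 47.2 ± 8.54 CPM and mt-Nd4 from 763 ± 192 to 338 ± 93.8 CPM, both subunits of complex I. mt-Nd5 (-1.36 ± 0.33) and mt-Nd3 (-1.21 ± 0.37) were not called over all genes. mt-Nd4 and mt-Nd3 share 60.8% and 97.6% of their words with nuclear copies and are uncertain. The list ranked lower (median -1.17, adjusted p = 0.000928), and adjusted p = 0.694 with an estimated correlation of 0.92. The median was -0.75 without control replicate 1. Mitochondrial transcripts took 1.79% ± 0.65 of counts in control (2.48%, 1.67% and 1.21% in replicates 1 to 3) and 0.949% ± 0.42 in Pex5-deficient libraries (0.840%, 0.592% and 1.42%), exact permutation p = 0.2. Ribosomal protein transcripts took 3.37% ± 0.17 and 4.21% ± 0.28 (exact permutation p = 0.1, the smallest possible). Nuclear genes of oxidative phosphorylation had 0 calls among 75, and 0 when adjusted over the list alone, with Ndufa6 at 0.58 ± 0.14, Ndufa8 at 0.33 ± 0.10, Ndufs3 at 0.29 ± 0.09 and Cox7a2 at 0.35 ± 0.12. Ndufs3 shares 19.9% of its words with a predicted gene. That list was not called (median 0.08, adjusted p = 0.0601), but passed without Pex5-deficient replicate 2 (5.3e-05) and control replicate 1 (0.0434), and with upper-quartile factors (0.0485), a mean of at least 5 CPM (0.0396), DESeq2 (0.0489) and limma-voom (0.0246). With the GC and length offset the shift was gone (median -0.00021, camera adjusted p = 0.836), as it was with the block added (-0.0024, 0.791). Mitochondrial fatty acid oxidation had 0 calls among 20, and 1 higher and 1 lower when adjusted over the list alone, Eci1 (0.39 ± 0.09) and Cpt1a, the gate of the pathway (-0.55 ± 0.13), with Acadl at 0.26 ± 0.09 and Echs1 at 0.28 ± 0.11 (list median -0.06, adjusted p = 0.558). Cardiolipin synthesis and remodelling had 0 calls among 13 and 0 when adjusted over the list alone, with Triap1 at 0.46 ± 0.14, Prelid2 at -0.61 ± 0.21, Hadha at -0.32 ± 0.13 and Pnpla8 at -0.43 ± 0.19 (median -0.08, adjusted p = 0.472). mt-Nd6 lost its call without Pex5-deficient replicate 1 (0.114) or 2 (0.0537) and control replicate 1 (0.104) or 2 (0.0903). mt-Nd4 lost its call without Pex5-deficient replicate 1 (0.155) and control replicate 1 (0.17), 2 (0.133) or 3 (0.0547).

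Genes of the integrated stress response ranked higher as a list with the preset correlation. 2 of 21 tested genes rose and 0 fell, and 10 rose and 1 fell when adjusted over the list alone. Gdf15, a secreted stress cytokine, rose from 22.2 ± 8.02 to 62.6 ± 12.9 CPM (1.49 ± 0.25) and Atf3, a stress transcription factor, from 14.4 ± 2.23 to 37.5 ± 12.9 CPM (1.37 ± 0.23). Atf4, the transcription factor at the centre of the response (0.40 ± 0.09, adjusted p = 0.0595), and its target Psat1, an enzyme of serine synthesis (0.93 ± 0.22), passed only when adjusted over the list alone. The list ranked higher by camera (median 0.41, adjusted p = 0.000447), and adjusted p = 0.694 with an estimated correlation. Immediate early genes, which respond to handling of cells, had 1 call among 19, Atf3, and 1 when adjusted over the list alone (median 0.21, adjusted p = 0.472), with Btg2 at -0.41 ± 0.12, Dusp1 at -0.95 ± 0.37 and Jund at 0.47 ± 0.21. Chaperones of the endoplasmic reticulum had 0 calls among 19, and 0 when adjusted over the list alone (median -0.17, adjusted p = 0.178), with Herpud1 at -0.44 ± 0.14, Sel1l at -0.24 ± 0.09, Xbp1 at -0.34 ± 0.16 and Hsp90b1 at -0.37 ± 0.19. Without Pex5-deficient replicate 1 that list ranked lower (median -0.26, adjusted p = 0.00286). Gdf15 lost its call without Pex5-deficient replicate 1 (0.0682) and control replicate 1 (0.0978). Atf3 lost its call without control replicate 1 (0.0978) or 2 (0.0748).

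Single genes of cell death changed. Among 22 tested p53 targets and apoptosis genes 2 rose and 1 fell, and 5 and 1 when adjusted over the list alone: Phlda3, a p53 target that restrains Akt, from 49.7 ± 3.31 to 161 ± 40.3 CPM (1.70 ± 0.18, adjusted p = 0.00373), the death agonist gene Bid from 3.29 ± 0.147 to 7.45 ± 1.09 CPM, and Bcl2l11, which encodes the death agonist Bim, down from 71.7 ± 2.25 to 51.2 ± 0.71 CPM. Cdkn1a, the p21 inhibitor of the cell cycle, had 0.44 ± 0.12 (adjusted p = 0.0914), and the list was not called (median 0.16, adjusted p = 0.125, but 0.0272 without Pex5-deficient replicate 2 and 0.0491 with library size only). Among 21 tested ferroptosis regulators Slc11a2, an iron transporter, rose from 11.7 ± 0.537 to 21 ± 1.58 CPM and Lpcat3 fell (-0.62 ± 0.11), 3 rising and 2 falling when adjusted over the list alone, with Gch1 at 0.67 ± 0.18 and Chac1 at 2.0 ± 0.56 (list median 0.11, adjusted p = 0.340, but 0.0407 without Pex5-deficient replicate 2). NRF2 antioxidant genes had 0 calls among 25, and 0 when adjusted over the list alone, with Gpx3 at 1.46 ± 0.35, Osgin1 at 1.46 ± 0.44, G6pdx at -0.42 ± 0.13 and Gstm1 at 0.82 ± 0.28 (median 0.15, adjusted p = 0.462, but 0.0272 without Pex5-deficient replicate 2). Pyroptosis and necroptosis genes had 0 calls among 15, and 0 when adjusted over the list alone, with Pycard at 0.36 ± 0.10, Ninj1 at 0.86 ± 0.26, Ripk1 at 0.50 ± 0.15 and Casp4 at 0.51 ± 0.17 (median 0.12, adjusted p = 0.127). Phlda3 and Slc11a2 kept their calls without any 1 library. Bid lost its call without Pex5-deficient replicate 1 (0.0676) or 3 (0.0546) and control replicate 1 (0.0852), 2 (0.0695) or 3 (0.0575). Bcl2l11 lost its call without Pex5-deficient replicate 1 (0.0944) or 3 (0.0732) and control replicate 1 (0.113), 2 (0.0681) or 3 (0.102). Lpcat3 lost its call without Pex5-deficient replicate 1 (0.0968) and control replicate 1 (0.111), 2 (0.0631) or 3 (0.0986).

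Genes of macrophages laden with lipid went both ways. Of 22 tested members of the lipid-associated macrophage signature 3 rose and 1 fell, and 4 and 2 when adjusted over the list alone. Trem2 (1.94 ± 0.19, adjusted p = 0.00314), Igf1 (2.89 ± 0.31) and the tetraspanin gene Cd63 (2.18 ± 0.47) rose and Apoe (-2.92 ± 0.37) fell, while Gpnmb, a glycoprotein of lysosomes, had 1.32 ± 0.33 (adjusted p = 0.0765). The list was not called (adjusted p = 0.999), and its median of -0.02 and its mean of 0.14 differed in sign, with camera's direction up. Lysosomal genes had 2 higher and 0 lower calls among 43, Ctsk (1.70 ± 0.30) and Cd63, and 3 higher when adjusted over the list alone, the third being Gla (0.52 ± 0.12). Man2b1 had -0.50 ± 0.15. The list's median of -0.03, mean of 0.05 and downward camera direction differed in sign (adjusted p = 0.826, but 0.0413 and upward without Pex5-deficient replicate 2). Among 19 tested scavenger and phagocytic receptors Msr1, which takes up modified lipoprotein, rose from 12.5 ± 3.09 to 39.4 ± 14.5 CPM and Fcgr2b, the inhibitory receptor for IgG, fell from 199.5 ± 31.1 to 78.2 ± 19.2 CPM, 1 rising and 3 falling when adjusted over the list alone, with Clec4n at -0.88 ± 0.22 and Axl at -0.74 ± 0.20 (median -0.15, adjusted p = 0.177). Cd63 lost its call without Pex5-deficient replicate 1 (0.145) or 3 (0.0819) and control replicate 1 (0.148) or 3 (0.142). Ctsk lost its call without Pex5-deficient replicate 1 (0.0893) and control replicate 1 (0.13), 2 (0.0831) or 3 (0.0986). Msr1 lost its call without Pex5-deficient replicate 1 (0.0648) and control replicate 1 (0.0546), 2 (0.0706) or 3 (0.0633). Fcgr2b lost its call without control replicate 1 (0.0541). Trem2, Igf1 and Apoe kept theirs without any 1 library.

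Of 17 tested inflammatory cytokines and NF-kB targets 4 rose and 0 fell, and 5 rose when adjusted over the list alone: Ccl3 from 1.8 ± 0.174 to 13.6 ± 8.34 CPM, Ccl4 from 0.325 ± 0.128 to 1.69 ± 0.648 CPM, Ccl22 from 6.63 ± 0.946 to 17.5 ± 3.68 CPM and Ccrl2, a chemokine-binding receptor, from 8.73 ± 1.78 to 20 ± 5.0 CPM. The list was not called (adjusted p = 0.125), and its median of -0.01 lay below 0 with a mean of 0.44 and camera's direction up. It passed with scaling by library size alone (median 0.17, adjusted p = 0.0213) and with DESeq2 (0.0202). Type I interferon response genes had 0 calls among 22, and 0 when adjusted over the list alone, with Trim30a at -0.35 ± 0.12, Oas1a at 0.36 ± 0.20 and Irf7 at -0.51 ± 0.29, of which Oas1a shares 40.2% of its words with another gene (median -0.17, adjusted p = 0.398, but 0.00336 without Pex5-deficient replicate 1). In glycolysis and hypoxia 1 of 25 genes rose and 1 fell, and 3 and 1 when adjusted over the list alone: the glucose transporter gene Slc2a1 from 16.1 ± 1.11 to 36.2 ± 12.1 CPM, and Pfkp, a phosphofructokinase, from 185 ± 22.9 to 125 ± 0.675 CPM. Aldoc had 0.79 ± 0.18 and Hk2 0.63 ± 0.15, and the list was not called (median -0.12, adjusted p = 0.607). Ccl3 lost its call without control replicate 1 (0.0681). Ccl4 lost its call without Pex5-deficient replicate 1 (0.111) or 3 (0.0635) and control replicate 1 (0.14), 2 (0.0747) or 3 (0.124). Ccl22 lost its call without control replicate 1 (0.0566). Ccrl2 lost its call without Pex5-deficient replicate 1 (0.0926) or 3 (0.0548) and control replicate 1 (0.111), 2 (0.0605) or 3 (0.0815). Slc2a1 lost its call without control replicate 1 (0.118), 2 (0.0774) or 3 (0.0821). Pfkp lost its call without Pex5-deficient replicate 1 (0.14), 2 (0.0546) or 3 (0.101) and control replicate 1 (0.141), 2 (0.0609) or 3 (0.15).

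Antigen presentation and proliferation genes ranked lower as lists with the preset correlation. Of 11 tested genes of antigen presentation on MHC class II, 2 fell and 0 rose, and 8 fell when adjusted over the list alone. H2-DMa, which loads peptides onto class II molecules, fell from 705 ± 45.2 to 322 ± 30.7 CPM (-1.13 ± 0.14, adjusted p = 0.00703) and H2-DMb2 from 26.7 ± 2.54 to 11.6 ± 2.41 CPM (-1.22 ± 0.17). Cd74, the invariant chain (649 ± 439.9 to 201 ± 51 CPM), H2-Aa (-2.0 ± 0.56) and H2-Ab1 (-1.74 ± 0.49) had larger but more variable differences and were not called over all genes. The list ranked lower (median -1.22, adjusted p = 0.000447), and adjusted p = 0.694 with an estimated correlation. Of 32 tested cell cycle genes 1 fell and 0 rose, and 2 fell when adjusted over the list alone: Bub1b, of the spindle checkpoint, from 67.1 ± 2.67 to 42.8 ± 3.32 CPM and, over the list alone, Top2a (-0.50 ± 0.12). Rrm2 had -0.39 ± 0.11 and Kif11 -0.53 ± 0.19. That list ranked lower (median -0.27, adjusted p = 0.000447), and adjusted p = 0.694 with an estimated correlation, with a median of -0.09 under scaling by library size alone. H2-DMa kept its call without any 1 library. H2-DMb2 shares 12.9% of its words with H2-DMb1 and is uncertain. H2-DMb2 lost its call without control replicate 1 (0.0541). Bub1b lost its call without Pex5-deficient replicate 1 (0.0648) and control replicate 1 (0.0678) or 3 (0.0578).

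**Figure D2:**
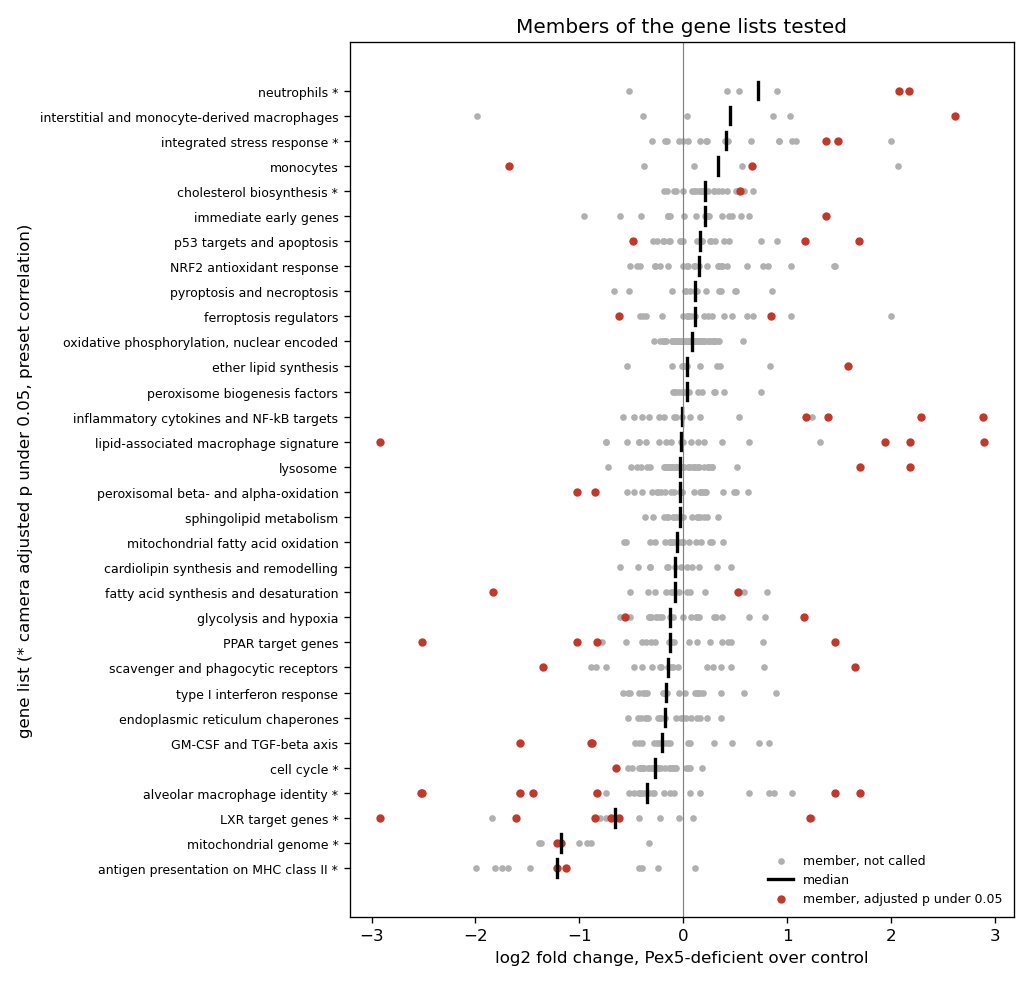
Log2 fold changes, Pex5-deficient over control, of the tested members of the 32 gene lists ranked with camera (1 point per gene, n = 3 libraries per group; red, adjusted p under 0.05; black bar, list median; asterisk, list called with the preset correlation). Antigen presentation on MHC class II had the lowest median at -1.22 and neutrophil markers the highest at 0.72, and 8 lists were called.

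Many markers of other cells stayed near 0, and others did not. The most abundant reached 462 CPM in 1 library (Wfdc21), 393 CPM (Fn1), 294 CPM (Gsr), 129 CPM (Epcam), 113 CPM (Sirpb1a), 112 CPM (Ramp2) and 107 CPM (Mmp8). Counted per library total without the scaling, of 12 B cell markers 12 stayed under 1 CPM in every library, of 18 T and NK cell markers 17, of 15 markers of endothelium and fibroblasts 14, of 12 dendritic cell markers 11, of 9 eosinophil markers 8, of 17 of lung epithelium 13 and of 7 erythroid ones 4. On that scale haemoglobin transcripts were seen almost only in Pex5-deficient replicate 2 (Hbb-bs at 2.86 CPM). Of the tested ones among these, Epcam fell (-2.75 ± 0.36), while Cdh1 (0.51 ± 0.18), Adgre4 (0.05 ± 0.76), Batf3 (0.58 ± 0.26), Klrb1c (-0.39 ± 0.36) and Ramp2 (-0.21 ± 0.10) were not called. Klrb1c shares 12.6% of its words with a predicted gene and Ramp2 64.1% with Vps25, which leaves both uncertain. Of 18 markers of interstitial and monocyte-derived macrophages 12 stayed under 1 CPM. C1qa, C1qb and C1qc, which such cells make abundantly, did not exceed 0.225 CPM of the unscaled total, which is also the level of 3 counts in the smallest library. Pf4 had -1.98 ± 0.59 and Sirpb1a, the most abundant tested marker, 0.04 ± 0.22, uncertain with 14.4% of its words shared with copies (6 tested, 1 higher, and 3 higher and 2 lower when adjusted over the list alone; median 0.45, adjusted p = 0.398). Of 12 monocyte markers 6 stayed under 1 CPM, Fn1, a matrix protein, fell from 350.3 ± 55.1 to 109.8 ± 48.5 CPM and Ace, a peptidase, rose from 15.7 ± 1.78 to 24.8 ± 3.56 CPM (6 tested, 2 higher and 1 lower when adjusted over the list alone; Gsr at 0.10 ± 0.17; median 0.33, adjusted p = 0.472). Of 14 neutrophil markers 7 had 0 counts in all 6 libraries, S100a9 and Ly6g among them, which allows up to 0.225 CPM in the smallest library. Of the 6 tested, the chemokine receptor gene Cxcr2 rose from 6.09 ± 2.53 to 27.8 ± 4.75 CPM and S100a8, a calcium-binding protein, from 6.66 ± 1.65 to 27.9 ± 12.8 CPM, with 3 higher when adjusted over the list alone, Mmp8 (0.90 ± 0.31) being the third, and Wfdc21 at 0.53 ± 0.31. This list ranked higher (median 0.72, adjusted p = 0.0221), and adjusted p = 0.694 with an estimated correlation, but passed with fry (0.00780), with a median of 0.48 without Pex5-deficient replicate 1. Cxcr2 kept its call without any 1 library. S100a8 lost its call without Pex5-deficient replicate 1 (0.0704) and control replicate 1 (0.0817), 2 (0.0695) or 3 (0.0545). Fn1 lost its call without control replicate 1 (0.102) or 3 (0.073). Ace lost its call without Pex5-deficient replicate 1 (0.0668), 2 (0.0636) or 3 (0.11) and control replicate 1 (0.163), 2 (0.148) or 3 (0.0741).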

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

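All alternatives were fixed before the data were examined. None of the 358 called genes changed sign under any of the 18 other fits. With 358 genes called, 362 were called with DESeq2 size factors, 382 with upper-quartile factors, 421 with library size only, 488 without a filter, 242 at a mean of at least 5 CPM, 324 with limma-voom, 346 with the robust test, 498 with the GC and length offset and 358 without mitochondrial, ribosomal protein and haemoglobin genes. DESeq2 called 755, and leaving out 1 library gave 76 to 523. Of the 358 calls, 354 were kept with DESeq2 size factors, 353 with upper-quartile factors and 337 with the GC and length offset. With library size only 240 of the 358 were kept, and 300 without Pex5-deficient replicate 2. Calls of at least 2-fold numbered 215, 125 at a mean of at least 5 CPM, where fewer genes were tested, and 68 to 268 with 1 library left out. With the replicate block 83 genes and 81 of at least 2-fold were called, and 211 with the GC and length offset together with the block. The labels do not say whether equal numbers pair the samples, and the counts gave no sign of it: deviations of same-numbered libraries correlated at -0.21, -0.06 and -0.41, and 0 of 6 libraries correlated best with its own number. That cannot exclude that samples were handled in pairs. The log2 fold change of Pex5 ranged from -0.039 (without Pex5-deficient replicate 2) to 0.10 with 1 library left out, and its call did not change under any setting. Of 32 lists 8 were called, 7 to 12 under the other fits, 7 to 11 with 1 library left out, 0 with an estimated correlation and 1, the neutrophil markers, with fry. Except for these, the cause was not tested.

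The direction of the list test turned only for lists that were not called with all libraries, and the values given are medians. For oxidative phosphorylation the median was -0.00021 with the GC and length offset and -0.0024 with the block added. For fatty acid synthesis the test turned without Pex5-deficient replicate 2 (-0.025), with medians from -0.13 to 0.012 as each library was left out. For sphingolipid metabolism it turned with the offset (-0.035) and without Pex5-deficient replicate 2 (-0.00036), with -0.035 to 0.0071 over the libraries left out. For lysosome it was 0.093 with library size only, -0.019 with DESeq2 and -0.066 with limma-voom, and -0.095 to 0.13 with 1 library left out, turning without Pex5-deficient replicate 2 (0.13) and control replicate 2 (-0.036). NRF2 genes ranged from -0.11, without Pex5-deficient replicate 1, where the test turned, to 0.32. Interferon genes ranged from -0.32 to -0.0090, turning at the latter without Pex5-deficient replicate 3. Glycolysis ranged from -0.21 to -0.031, turning at the latter without Pex5-deficient replicate 2. For the lipid-associated macrophage signature the median was -0.011 with DESeq2 size factors, -0.0041 with upper-quartile factors, -0.016 without a filter, -0.068 with the block, -0.14 with the offset, -0.18 with both and -0.019 with a prior count of 0.5. It ranged from -0.24 to 0.19 with 1 library left out, turning without Pex5-deficient replicates 1 (-0.076) and 3 (-0.24) and control replicates 1 (0.0049) and 3 (-0.078).

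Genes that turned were not called in any of these settings. The Pparg log2 fold change ranged from -0.0071 to 0.14 with 1 library left out, and the Chil3 log2 fold change from -0.084 to 0.47. The Gsr log2 fold change ranged from -0.11 to 0.22. The Sptlc1 log2 fold change was 0.018 with library size only. The Sirpb1a log2 fold change was -0.012 with the block, -0.017 with the GC and length offset and -0.041 with both, and -0.19 to 0.29 with 1 library left out. The Adgre4 log2 fold change, of a gene under 1 CPM on average, ranged from -0.39 to 1.30. Of the values of named genes 2661 kept direction and side of the threshold, 117 crossed to called, 268 crossed to not called and 13 turned. Of those of lists 604 stayed, 24 crossed to called, 21 crossed to not called and 24 turned. A model with sex as a covariate was not run, since all 6 libraries expressed genes of the Y chromosome. Changes under 2-fold were often beyond reach with 3 libraries per group.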

Other observations

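The genes of the first 2 paragraphs, the counts around Pex5 and around the H2- genes, and the tests on cells of other types, shared copies and MITF targets were chosen after the results had been seen; the tests on GC content, scaling, single libraries, the linked locus and splits were set before, though the first pattern was reworded once its result was known. Myo5a, a myosin motor, rose from 13.9 ± 4.14 to 60.2 ± 9.7 CPM (adjusted p = 0.00334) and Mreg, a regulator of vesicle transport, from 10 ± 0.446 to 45.9 ± 13.6 CPM (adjusted p = 0.00258), and both calls held whichever library was left out. Epas1, which encodes the hypoxia factor HIF-2 alpha, rose from 16.9 ± 7.2 to 101 ± 18.2 CPM (adjusted p = 0.00406) and kept its call likewise. Ch25h, which makes 25-hydroxycholesterol, rose from 37.1 ± 17.8 to 156 ± 69.9 CPM and Txnip, a sensor of glucose, fell from 1534 ± 284 to 505 ± 192 CPM. The complement receptor gene C5ar1 fell from 621 ± 59.9 to 271 ± 67.6 CPM. Ch25h lost its call without Pex5-deficient replicate 1 (0.111) or 3 (0.059) and control replicate 1 (0.145) or 3 (0.0853). Txnip lost its call without Pex5-deficient replicate 1 (0.0793) and control replicate 1 (0.114), 2 (0.0849) or 3 (0.0524). C5ar1 lost its call without Pex5-deficient replicate 1 (0.0813) and control replicate 1 (0.0826) or 2 (0.0579).

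The Clec4 family of C-type lectin receptors, which lie together on chromosome 6, had 7 tested members, of which 4 fell and 1 rose. Clec4a3 fell from 432 ± 128 to 159 ± 28.4 CPM, Clec4a2 from 140.1 ± 28.2 to 66.2 ± 9.45 CPM, Clec4b1 from 58.9 ± 6.65 to 33.4 ± 4.2 CPM and Clec4a1 from 4.01 ± 1.19 to 1.05 ± 0.287 CPM, while Clec4d, an activating receptor, rose from 12.7 ± 3.05 to 39.5 ± 20.3 CPM and Clec4n had -0.88 ± 0.22 (adjusted p = 0.0734). Clec4a3 lost its call without Pex5-deficient replicate 1 (0.0726). Clec4a2 lost its call without Pex5-deficient replicate 1 (0.0676). Clec4b1 lost its call without Pex5-deficient replicate 1 (0.0572) and control replicate 1 (0.0724) or 3 (0.0538). Clec4a1 lost its call without Pex5-deficient replicate 1 (0.0523) and control replicate 1 (0.0724) or 3 (0.073). Clec4d lost its call without Pex5-deficient replicate 1 (0.0924) or 3 (0.0643) and control replicate 1 (0.145), 2 (0.142) or 3 (0.0985). Within 5 Mb of the start of Pex5, 8 of 80 tested genes were called, with 2.60 expected (odds ratio 3.36, 95% interval 1.39 to 7.05, Fisher's exact p = 0.00436), these being Bid, Clec4a1, Clec4a3, Clec4b1, Clec4a2, Clec4d, Lpcat3 and Vwf. The Clec4 genes are neighbours named above for their changes, and Fisher's test counts them as independent. Without them Bid, Lpcat3 and Vwf remain, beside 2.60 expected for the whole window. The p is therefore no independent sign of an effect of the locus. Bid lost its call without Pex5-deficient replicate 1 (0.0676) or 3 (0.0546) and control replicate 1 (0.0852), 2 (0.0695) or 3 (0.0575). Lpcat3 lost its call without Pex5-deficient replicate 1 (0.0968) and control replicate 1 (0.111), 2 (0.0631) or 3 (0.0986). Vwf lost its call without control replicate 1 (0.0627). The classical class I genes H2-K1 and H2-D1 measured 4687 ± 716 to 1839.5 ± 933 CPM and 8613 ± 1028 to 4735 ± 1723 CPM, with adjusted p = 0.123 and 0.23.

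The first pattern is that 5 of 28 alveolar macrophage identity genes fell and 2 rose while Trem2, Igf1 and Cd63 rose, although the list's call was lost with an estimated correlation (adjusted p = 0.780) and without Pex5-deficient replicate 2 (0.272) or control replicate 2 (0.144), and the call of Cd63 without Pex5-deficient replicate 1 (0.145) or 3 (0.0819) and control replicate 1 (0.148) or 3 (0.142). Macrophages from the interstitium or the blood would bring C1qa, C1qb and C1qc, whose highest level in a Pex5-deficient library was 0.225 CPM of the unscaled total (list median 0.45, bootstrap 95% interval -1.18 to 1.82), and monocytes Ly6c2, Plac8 and F13a1, whose highest was 0.0750 CPM (0.33, -1.03 to 1.36), although Ace rose by 0.66 ± 0.14, a call that ended without Pex5-deficient replicate 1 (0.0668), 2 (0.0636) or 3 (0.11) and control replicate 1 (0.163), 2 (0.148) or 3 (0.0741), and Hp (2.07 ± 0.53, adjusted p = 0.0787) and Treml4 (0.57 ± 0.27, adjusted p = 0.296) were not called. The neutrophil markers moved with the pattern (median 0.72, -0.049 to 2.12, adjusted p = 0.0221, and adjusted p = 0.694 with an estimated correlation), Cxcr2 by 2.17 ± 0.28 and S100a8 by 2.07 ± 0.35, but neutrophils would also bring S100a9, Retnlg and Ltf, whose highest level was 0.150 CPM. The genes set against each kind of cell were picked after the results were seen, and the interval of each list median allows a rise. S100a9 and Retnlg had 0 counts in every library, so whether they can be counted here is not known. These low levels are therefore no independent test of such cells. With the GC and length offset 100% of the 11 called members of both lists stayed called in the same direction, which argues against that bias as the cause. A change of state within resident macrophages of the Vav1cre/+ Pex5fl/fl mice may remain, as a hypothesis, and a change in which resident cells survive or passed the sort was not tested.

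The second pattern is the lower level of mitochondrially encoded transcripts. Of 9 tested genes 2 were called, mt-Nd6 and mt-Nd4, and each kept its call in only 2 of the fits without 1 library. The list had adjusted p = 0.694 by camera with an estimated correlation and 0.254 with fry. Their share of counts had an exact permutation p of 0.2. The choice among the scalings tried did not remove the difference, since the median of the 9 tested genes stayed at or below -1.04 under each (highest upper bootstrap bound -0.81). These scalings move all genes together, and the median of all genes was -0.00077 with TMM and 0.17 with library size only. So small a shift could not have removed the difference, whatever its cause. The bootstrap bounds are over 9 genes with an estimated correlation of 0.92 and do not measure the spread between libraries. Whether 1 library decides the size cannot be told apart from a difference between the groups, because the median was -0.75 without control replicate 1 and the highest upper bootstrap bound with a library left out was -0.39. RNA quality or a difference in mitochondrial content may each lie behind it, and neither was tested.

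The third pattern is the lower level of some MHC genes of chromosome 17. Of 22 tested H2- genes 4 fell, 0 rose and the others were not called. H2-DMa kept its call without any 1 library, while H2-Q7, H2-Q6 and H2-DMb2 each lost it without at least 1 library. The class II list had adjusted p = 0.694 by camera with an estimated correlation. Reads shared between near-identical copies would spare the distinct ones, but the 13 H2- genes with under 5% of words shared had a median of -1.13 (bootstrap interval -1.81 to -0.51). That interval is over genes and does not measure the spread between libraries. Of the called genes only H2-DMa (0% shared) was among these 13. H2-Q7, H2-Q6 and H2-DMb2 shared 12.4%, 10.7% and 12.9% of their words, so their own falls stay uncertain. Alleles carried along from another strain cannot be told apart from a lower expression: without the H2- genes chromosome 17 held 13 calls among 553 genes with 17.8 expected (odds ratio 0.713, 95% interval 0.373 to 1.25, Fisher's exact test), but a linked segment would raise calls only near the locus. Within 5 Mb of the H2- genes 4 of 147 other genes were called with 4.74 expected (odds ratio 0.839, 0.224 to 2.21), too few to decide, and these changed widely on the log2 scale: Btnl4 by 5.36 ± 0.72, Btnl6 by 2.78 ± 0.41, Gabbr1 by -3.08 ± 0.64 and Cpne5 by -1.38 ± 0.19, the call of Btnl6 ending without control replicate 1 (0.0541) and that of Gabbr1 without Pex5-deficient replicate 1 (0.105), 2 (0.0627) or 3 (0.0771) and control replicate 1 (0.125) or 3 (0.113), while without control replicate 2 Gabbr1 did not pass the filter and was not tested.

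A hypothesis drawn from Mlph, Mreg, Myo5a, Gpnmb, Ctsk and Cd63 was that higher activity of the MITF and TFE transcription factors, which drive pigment and lysosome genes, could explain them. It was tested on 26 other targets, put together after the called genes were seen and with those left out, so that 0 of them were called by construction. Of these 19 were tested, of which 13 had a positive and 6 a negative fold change. Their median was 0.0952 (bootstrap interval -0.03 to 0.19) and camera gave p = 0.304 by its model, or 0.327 with an estimated correlation, which decides nothing, because leaving out called genes pulls the median towards 0. The hypothesis stays open.

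The 6 libraries can be split into groups of 3 in 10 ways, so the share of splits with a result as large is never under 0.1 and cannot go under 0.05. The real split called 358 genes, with 28 as the highest among the others, and 215 genes of at least 2-fold, with 28 as the highest, each being 1 of 10 splits with as many. It called 8 gene lists, with 12 as the highest among the others, and 7 of 10 splits gave as many. The number of lists called with the preset correlation thus does not set the real grouping apart, and the list calls given above carry that limit.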
